A study of Mus musculus with 2 samples.

How the data were processed

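The deposited values were read as counts per the file headers, which name Cell Ranger 6.0.1, and each was a whole number of unique molecular identifiers (UMIs) per gene and barcode. Alignment was to mm10 per the submitters' processing notes, and the annotation release was not given in the sources used here. The matrices held 32285 genes. Identifiers of 484 of 484 genes used in lists and markers matched the reference annotation (GRCm38, GENCODE M21), and 4 symbols chosen beforehand were absent from the matrices (Ctgf, Ero1a, Ero1b and Tmem27).

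The settings below were fixed before the data were examined, together with 17 alternatives, 32 gene lists and the markers of 20 cell types. Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 15% of UMIs from mitochondrial genes. Scrublet was run per library with an expected rate of 0.06. Its automatic threshold failed, marking 0.0279% of the WT and 0.0132% of the DB barcodes, so the limit was set at the 94th percentile of scores, and the barcodes above it were removed (377 or 5.26% in WT, 425 or 5.62% in DB). These are fewer than 6% because many barcodes share a score and those equal to the limit were kept. Counts were scaled to 10000 per cell and logged. The libraries were clustered together without integration on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, with list members, markers, mitochondrial and ribosomal genes held out of the clustering. Cell types are not in the deposited records, so names were rebuilt from the markers, and a class is called by the type it resembles. A name needed at least 3 markers 2-fold or more above the 10th percentile of clusters, a mean log2 score of at least 1, and 10 leading genes that did not go against it or come from the cell cycle. A cluster of another name whose median cell drew more than 10% of its UMIs from Ins1 and Ins2 was left unnamed as mixed. That limit was set after the clusters were seen and kept 5.75% of WT and 3.32% of DB cells out of the named classes.

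UMIs were summed per class and library for classes of at least 50 cells in each library, and scaled by trimmed mean of M values (TMM). edgeR and DESeq2 gave scaling factors and nothing else, and no test was run because each genotype had 1 library. A gene was measured with 50 summed UMIs or more in either library. Higher or lower means a ratio of at least 1.5-fold. Intervals are 95%, exact binomial for shares and conditional binomial (Poisson counts) for ratios of sums, and they hold counting error only, without differences between mice or preparations. Where a library had 0 UMIs, the ratio is a lower bound from 3 counts. A gene was named when it had at least 50 UMIs, 50 CPM in either library, a 2-fold ratio, an interval outside 1.5-fold and at least 50% of the whole-library level in the library where it was higher. Up to 12 such genes each way were named in beta cells, 6 in other classes, and the 4 members of largest ratio in each list. List medians were placed among 10000 random lists matched for level in 20 bins, with intervals from 2000 bootstrap draws over members. Shares of cells with a transcript were taken after thinning each cell to 2000 UMIs. A cell was called cycling with 2 of 10 cycle genes.

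A self-test drew Poisson counts around the mean profile of each class, changed the level of 200 genes by known folds in either direction and ran the same comparison. It held counting error only, without differences between mice, preparations, free RNA or cell mix. Its rates are therefore not the error rates of the comparison between the 2 libraries. In beta cells (12755 genes) 0.350% of genes left alone reached 1.5-fold, as did 57.6% of genes changed 1.5-fold and 100% of those changed 2-fold or 4-fold. Intervals held the true ratio for 94.9% of genes left alone and for 93.9%, 93.8% and 90.8% at the 3 fold sizes. In T or NK cells (1703 genes) the shares reaching 1.5-fold were 2.95% of genes left alone and 50.0%, 95.0% and 100% of genes changed by those folds. A list of 20 members raised together stood at percentile 100 in both classes, and a list left alone at percentile 2.04 in beta cells and 64.3 in T or NK cells.

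Settings were varied in the cell filter (none, or 1000 genes, 2000 UMIs and 10% mitochondrial), doublet removal, the variable genes, Leiden resolution (0.5 and 2), separate clustering, the scaling (CPM, meaning counts per 1000000 UMIs, of all UMIs, CPM outside hormone, mitochondrial and acinar genes, DESeq2 median ratio), cell weighting, subtraction of free RNA, the minimum count (10 and 200), the size (2-fold) and the thinning depth. Free RNA was estimated from genes in cells of types that do not make them, and the planned estimate was set by acinar enzymes (18.1% of the whole-library level in WT, 56.5% in DB). A hormone estimate added later gave 3.91% and 6.90%. It was 1 of 6 settings added after the data were seen, with leaving out cells of mixed insulin, leaving out the beta cluster led by Nos2, leaving out the mesenchymal cluster with under 50 cells in a library, list members of at least 10 CPM, and endocrine classes by a leading hormone of at least 5% of UMIs. Plain CPM moved the all-gene median against TMM by 0.20 log2 in beta cells, -0.17 in PP, -0.18 in delta, -0.11 in endothelial and -0.20 in macrophage cells, and CPM outside hormone genes moved it by -0.22 in macrophages and -0.19 in ductal cells. Software was Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0, with seed 1.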

Results

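Pancreatic islets of 9-week-old BKS mice were profiled by droplet-based single-cell RNA sequencing, with islets of 3 mice per genotype in 1 library. The WT library came from Lepr wild-type controls and the DB library from db/db mice, which lack a working leptin receptor and develop obesity and type 2 diabetes. The WT library held 12259 barcodes and 157860264 UMIs, and the DB library 9756 barcodes and 165562009 UMIs. After filtering, 6787 WT and 7139 DB cells remained, with a median of 16387 and 16787 UMIs and 3294 and 3364 genes per cell. The kept cells carried 88.5% and 89.2% of the UMIs, with a median of 2.18% and 2.42% from mitochondrial genes. Of all barcodes, 41.6% in WT and 22.5% in DB failed the filter, and these drew a median of 76.3% and 61.0% of their UMIs from mitochondrial genes. Both libraries came from males by their transcripts, with 15 and 14 UMIs of Xist, the X-inactivation transcript, against 6474 and 6980 UMIs of Ddx3y from the Y chromosome. Lepr had 9 UMIs in WT and 8 in DB, and its 3' tags cannot show the db mutation. Because cells cannot be traced to mice, every difference below is between 1 library and another.

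The first question was which cell types each genotype contributed. The cells formed 23 clusters, and beta-like cells were the largest class, with 51.8% of WT cells (95% interval 50.6 to 53.0) and 48.7% of DB cells (47.5 to 49.9). The libraries shared the beta clusters unequally. WT beta-like cells lay mostly in clusters 0 and 1 (2066 and 1417 WT cells against 64 and 117 DB cells), and DB beta-like cells mostly in clusters 2, 4 and 7 (1451, 987 and 857 DB cells against 10, 22 and 2 WT cells). A cluster drawn mostly from 1 library can reflect the library and need not be a cell state. Alpha-like cells made up 12.5% of WT and 4.08% of DB cells, a ratio of 0.327 (0.288 to 0.372). PP-like cells, which make pancreatic polypeptide, went the other way, from 0.840% in WT to 4.43% in DB, or 5.27 times the WT share (3.98 to 6.97). Delta-like cells, the somatostatin makers, took 7.37% and 6.47%. Among endocrine cells alone, alpha-like cells were 845 of 4919 in WT and 291 of 4545 in DB, PP-like cells 1.16% and 6.95%, and beta-like cells 71.5% and 76.5%.

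Among the named classes outside the endocrine cells, ductal-like cells showed the largest difference. They were 1.86% of WT and 7.94% of DB cells, a ratio of 4.28 (3.54 to 5.17). Macrophage-like cells were fewer in DB (4.54% and 2.06%, ratio 0.454), B-like cells more frequent (5.67% and 9.50%, ratio 1.67), and dendritic-like cells, marked by Ccr7 and Fscn1, also more frequent (0.575% and 1.23%, ratio 2.15). T or NK-like cells were alike (1.97% and 2.02%). Endothelial-like cells (2.61% and 1.82%), mesenchymal-like cells (3.33% and 2.76%) and acinar-like cells (0.530% and 0.644%) differed less. The acinar-like class joined cluster 21 (36 WT and 6 DB cells) and cluster 22 (0 and 40), so its similar shares need not hold the same cells. Its ratio was 1.21 (0.786 to 1.88), 1.24 with doublets kept and 1.25 without mixed insulin cells. It was 0.979 without a filter, 0.409 with every variable gene and 0.371 at Leiden resolution 2. Clusters left without a name held 6.44% of WT and 8.36% of DB cells, and the mixed clusters among them 5.75% and 3.32%. Cells were also named by their leading hormone, taking those with at least 5% of UMIs from it, which gave 12.8% and 5.10% for alpha-like cells and 0.855% and 3.81% for PP-like cells. For alpha-like cells 117 WT and 71 DB cells lay near that limit, and for PP-like cells 9 and 25. Over every barcode, before filtering, the leading-hormone ratio was 0.518 for alpha-like and 5.80 for PP-like cells.

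Several of these shares depended on the cell filter and the clustering. Without a filter PP-like cells merged with alpha-like cells, and the joint ratio was 0.833, which cannot be set beside the alpha ratio alone. Keeping likely doublets brought the PP ratio to 1.64, while clustering on every variable gene raised it to 8.91. Under the stricter filter the B-like ratio turned to 0.933 and the T or NK-like ratio was 0.481. The beta-like ratio stood above 1 in some settings (1.17 without a filter, 1.02 with every variable gene, 1.01 with the stricter filter). So did the delta-like ratio (1.01 without a filter) and the mesenchymal-like ratio (2.05 with every variable gene, 2.04 at the lower Leiden resolution, 1.24 without a filter). At that resolution the mesenchymal-like class held 248 WT and 532 DB cells. Those are the counts of its main cells (226 and 197) with the unnamed cluster 12 (22 and 335) added. With every variable gene the class held 248 and 534 cells.

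**Figure D1:**
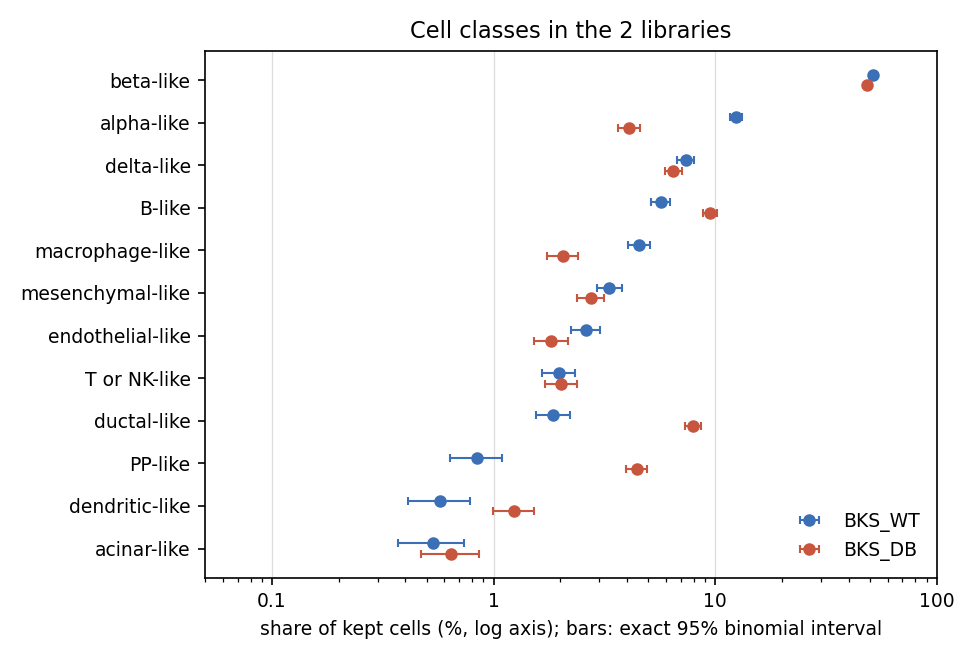
Share of kept cells in each class of the WT and DB libraries, on a log axis. Bars are exact 95% binomial intervals and hold counting error only.

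The second question was how db/db beta-like cells differ from control beta-like cells, compared over 3517 WT cells (mostly clusters 0 and 1) and 3476 DB cells (mostly clusters 2, 4 and 7) with median depths of 26596 and 26701.5 UMIs. DB beta-like cells had lower levels of genes that define a mature beta cell. They had higher levels of the hormone genes Cck and Gast, of genes used as marks of dedifferentiation, and of NF-kB targets. Genes of the immediate early and dissociation response were higher as well. Insulin transcripts stayed abundant in both libraries. In all, 13074 genes were measured.

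Of 24 measured genes of beta cell identity and maturity, 17 were lower in DB, 1 was higher and 6 lay between. The median log2 ratio was -1.21 (bootstrap interval -1.52 to -0.60), at percentile 0 of the random lists, and each member reached 50% of its whole-library level in these cells. Mafa (chromosome 15 of GRCm38, 75745490 to 75748228), a transcription factor of the insulin gene, had 360 counts per 1000000 UMIs (CPM) in WT and 14.5 in DB, 24.9-fold lower (23.7 to 26.2). Slc2a2 (chromosome 3, 28697903 to 28731359), which encodes the glucose transporter GLUT2, was 10.8-fold lower (113 and 10.5 CPM). Trpm5, a cation channel of stimulated insulin release, was 11.1-fold lower (33.0 and 2.97 CPM), and Sytl4, a granule docking protein, 5.70-fold lower. Ucn3, a late maturity marker, differed less, with 126 and 53.0 CPM. Ins1 was 2.06-fold lower while Ins2 was 1.17-fold lower and Iapp, the amyloid peptide gene, 1.12-fold higher. The granule zinc transporter gene Slc30a8 was lower as well (181 and 39.7 CPM), as was Pcsk1, a proinsulin convertase gene (289 and 128 CPM). In contrast, the granins Chgb and Scg2 were higher (843 and 2991 CPM, 1509 and 4146 CPM), so the 28 genes of granules and exocytosis together had a median of -0.06 (5 higher, 2 lower).

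Other genes were lower in DB as well. Lpl, the lipoprotein lipase gene, had 82.8 CPM in WT and 3.25 in DB. Cox6a2, a subunit of the respiratory chain, was 10.6-fold lower, Ppp1r1a, a phosphatase inhibitor gene, 9.45-fold lower and the transferrin receptor gene Tfrc 6.28-fold lower. The receptor gene Igf1r, for insulin-like growth factor, had 391 and 70.4 CPM. Fam151a (13.5-fold), Ttc28 (4.54-fold) and Ctnnal1 (4.51-fold) completed the genes lower in DB. Despite Cox6a2, the 65 genes of oxidative phosphorylation were largely level, with 61 between the limits, 3 lower and a median of -0.27, or -0.07 under plain CPM. The 13 mitochondrially encoded genes lay between the limits (median -0.17). Of 18 glycolysis genes 5 were lower and 3 higher (median -0.39), and that median ranged from -0.81 with free RNA subtracted to -0.19 under plain CPM. Pfkfb3, which makes an activator of glycolysis, was 17.0-fold higher and the glucose transporter gene Slc2a1 2.32-fold lower.

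The largest ratio in beta-like cells belonged to Cck (chromosome 9, 121489824 to 121495694), the gut hormone cholecystokinin, with 30 UMIs in WT and 46282 in DB, a 1292-fold difference (905 to 1914). Gast (chromosome 11, 100334407 to 100336996), which encodes the stomach hormone gastrin, had 1.32 and 53.6 CPM, 40.7-fold higher. Aldh1a3 (chromosome 7, 66390890 to 66427517), a retinaldehyde dehydrogenase gene used to mark dedifferentiated beta cells, had 0.541 and 25.4 CPM, 47.0-fold higher (35.6 to 63.3). These belong to a list of 15 dedifferentiation genes, of which 10 were higher and 3 lower (median 1.72, bootstrap interval 0.42 to 4.64, percentile 100). The list also holds the hyaluronan receptor gene Cd44 (24.9-fold), the hormone carrier gene Serpina7 (8.64 and 103 CPM) and the surface protein gene Cd24a (10.1-fold), while Npy, the neuropeptide Y gene, went the other way, with 12.9 CPM in WT and 0.0888 in DB. Higher genes outside that list included the Ras activator gene Rasgrf2 (16.5-fold) and Gc, a vitamin D carrier gene (15.9-fold). Car8, a carbonic anhydrase relative, had 9.40 and 109 CPM, and Pamr1 and the secreted glutathione peroxidase gene Gpx3 were 9.05-fold and 8.71-fold higher. Gc and Gpx3 also belong to 9 measured alpha cell identity genes, of which 6 were higher, together with Ttr, the transthyretin gene (270 and 1388 CPM). That median was 1.10 but ran to 4.89 with free RNA subtracted. The hormone genes of other islet cells, Gcg (1.62-fold), Sst (2.51-fold), Pyy (4.80-fold) and Ppy (5.75-fold), were higher in DB beta-like cells too, each below 50% of its whole-library level.

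To see whether these ratios came from a few cells, transcripts were counted per cell after thinning to 2000 UMIs, with 3454 WT and 3457 DB cells (63 and 19 left out). Cck was found in 2 WT cells, or 0.0579% (0.00701 to 0.209), and in 31.3% of DB cells (29.8 to 32.9), against 0.597% and 62.5% unthinned. In endothelial-like cells, taken as background at median depths of 9626 and 5083.5 UMIs, Cck was found in 0 of 174 WT cells (exact upper limit 2.10%) and 3.31% of DB cells. Gast was present in 7 WT and 242 DB beta-like cells (3.13% and 39.7% unthinned) and in 4 of 130 DB endothelial-like cells unthinned (3.08%). The ratios of these shares were 541 for Cck (135 to 2164, with the WT share resting on 2 cells) and 34.5 for Gast thinned, and 105 (68.3 to 161) and 12.7 unthinned. Aldh1a3 was present in 0.116% and 4.66%, and unthinned in 1.02% and 39.0%, beside 0.826% of DB endothelial-like cells thinned. Ppy was found in 6.60% and 36.7% of beta-like and 5.75% and 50.4% of endothelial-like cells, and unthinned in 41.5% and 96.5% against 28.8% and 84.6%, and since the endothelial-like cells are shallower these shares do not separate free Ppy RNA from Ppy of beta-like cells. Cycle genes were found in 0.199% of WT and 0.748% of DB cells unthinned (ratio 3.76, 1.63 to 8.65), and thinning left 1 such cell, in DB, too few to compare.

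**Figure D2:**
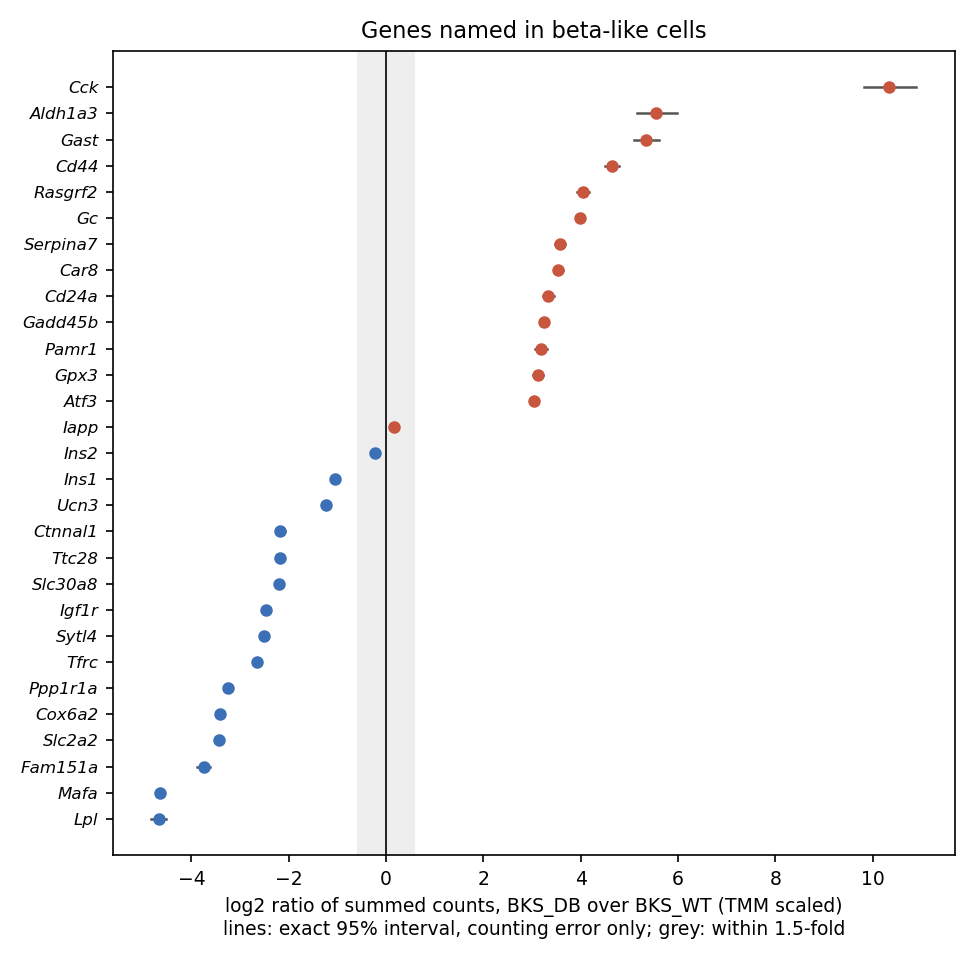
Log2 ratios (DB over WT) of the genes named in beta-like cells, with 95% counting intervals. The grey band marks ratios within 1.5-fold.

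NF-kB targets and genes of the immediate early and dissociation response were also higher in DB beta-like cells. Of 20 measured NF-kB targets and chemokines, 18 were higher and 1 was lower, with a median of 2.96 (1.93 to 5.37) at percentile 100. The largest ratios were in the chemokine genes Cxcl2 (0.276 and 58.4 CPM), Cxcl1 (0.743 and 113 CPM) and Ccl2 (0.478 and 53.3 CPM) and in the cytokine gene Tnf (0.0531 and 7.56 CPM), each below 50% of its whole-library level. After the values were seen, Icam1 and Nfkbia were singled out because they reach that level. Icam1, an adhesion molecule gene, had 0.340 and 26.6 CPM, and Nfkbia (chromosome 12, 55489410 to 55492647), the NF-kB inhibitor gene, 66.7 and 539 CPM. In all, 9 of the 20 reached 50% of their library level, and 7 were higher after subtraction of free RNA. Outside cluster 7, free RNA cannot be told apart as the source. In clusters 2 and 4, 7 of 20 members stood at least 1.5-fold above the class where each is lowest. Icam1 there (7.09 CPM) stood below alpha-like cells (9.75 CPM), its lowest class. Of 24 immediate early and dissociation response genes 19 were higher and 0 lower (median 1.23, percentile 100). They included the transcription factor genes Egr2 (12.4-fold) and Fosb (15.8 and 112 CPM), the RNA decay gene Zfp36 (4.47-fold) and the heat shock gene Dnajb1 (4.42-fold). This list also covers the response to cell dissociation. With 1 library per genotype, preparation of the cells cannot be told apart from genotype as its source. The stress genes Gadd45b (18.4 and 174 CPM) and Atf3 (14.8 and 121 CPM) were also higher.

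Antigen presentation genes were higher in DB beta-like cells, with 12 of 19 higher, 2 lower and a median of 0.84, although 7 were higher at 2-fold or with free RNA subtracted and 6 among members of at least 10 CPM. Examples were the class I genes H2-Q6 (0.870 and 5.23 CPM) and H2-T22 (5.73 and 18.6 CPM) and the immunoproteasome gene Psmb10 (25.9 and 64.7 CPM). Interferon-stimulated genes had no common direction (10 higher, 5 lower, median -0.18), with the chemokine gene Cxcl10 12.2-fold and the transcription factor gene Irf1 8.09-fold higher. Their median was -0.37 without cluster 7 and -0.96 with free RNA subtracted.

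Genes of protein folding and of the integrated stress response differed little as groups. Of 27 endoplasmic reticulum chaperone and degradation genes 25 lay between the limits (median 0.18, 0.38 under plain CPM and 0.29 with free RNA subtracted), though Derl3, a degradation factor gene, was 2.82-fold higher and the co-chaperone gene Dnajc3 had 223 and 441 CPM. Of 25 integrated stress response genes 7 were lower and 4 higher (median -0.31), with the pseudokinase gene Trib3 2.63-fold lower and the phosphatase subunit gene Ppp1r15a 2.62-fold higher. Among 26 oxidative stress genes 7 were higher and 4 lower (median 0.00), and these included Prdx4, a peroxiredoxin gene (3.64-fold higher), and the antioxidant genes Hmox1 (145 and 40.6 CPM) and Nqo1 (4.23-fold lower). Of 7 leptin signalling genes 4 were higher (median 0.89), among them Socs3 (11.2 and 28.5 CPM) and Cish (7.44 and 19.3 CPM), which encode feedback inhibitors of cytokine receptors.

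Among the clusters holding most DB beta-like cells, cluster 7 had Cck, Defb1, Gbp6, Nos2 and Tnfrsf11b among its leading genes. Those genes were not ranked against clusters 2 and 4 alone, so they need not set it apart from these. Cluster 7 was singled out for comparison within the DB library after the clusters were seen, because Nos2 was among its leading genes. The comparison is therefore not independent of that choice. Compared with clusters 2 and 4 (2438 cells), its 857 cells had 16 of 20 NF-kB targets higher (median 1.72, 0.89 to 3.60), such as the chemokine genes Ccl2 (5.90 and 201 CPM) and Cxcl2 (9.56 and 212 CPM). Of 22 interferon-stimulated genes 13 were higher (median 1.09), including Gbp2, a guanylate-binding protein gene (2.37 and 17.3 CPM). Antigen presentation differed less (8 of 18 higher, median 0.50), and 6 of 24 identity genes were lower (median -0.29), such as Ucn3 (68.4 and 37.7 CPM).

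The third question was whether the other islet hormone cells differ in the same way. In alpha-like cells (845 and 291 cells) Gcg, the glucagon gene, was 1.04-fold lower and Ppy 3.71-fold higher. Higher genes were the secreted protein gene Spp1 (316 and 2844 CPM), the acute phase gene Serpina3n (5.90 and 91.4 CPM), the crystallin gene Crybb3 (13.7-fold), Tacc2 (11.3-fold), the uroplakin gene Upk3a (6.12-fold) and the G protein regulator gene Rgs4 (4.58-fold). Lower genes were the detoxifying enzyme genes Akr1c19 (4.52-fold) and Gstp1 (4.06-fold), Tmem108 (3.37-fold), the phosphodiesterase gene Pde10a (3.22-fold), Scand1 (2.98-fold) and the retinol carrier gene Rbp4 (822 and 277 CPM). Of 6 measured NF-kB targets 5 were higher (median 1.91, 4 of 6 at 50% of their library level or more), a direction that turned to -0.63 with free RNA subtracted.

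In delta-like cells (500 and 462 cells) Sst was 1.18-fold lower, and 29.4% of WT and 40.5% of DB cells drew more than 10% of their UMIs from insulin, so some transcripts are those of beta cells. Ins2, 1.79-fold higher there, turned to a log2 ratio of -0.14 with every variable gene, -0.06 at the higher Leiden resolution and -0.47 with free RNA subtracted. Cck (10 and 2290 UMIs) and Serpina7 (17.2-fold) were higher as in beta-like cells, next to Cxcl10 (1.04 and 52.4 CPM), Nfkbia (6.92-fold), Irf1 (30.1 and 154 CPM) and Tacc2 (16.3 and 102 CPM). Lpl (7.02-fold), the actin-binding peptide gene Tmsb15b2 (147 and 25.3 CPM), Gcg (5.71-fold), the small heat shock gene Hspb1 (4.14-fold), Akr1c19 (3.79-fold) and the alpha cell transcription factor gene Mafb (58.0 and 16.3 CPM) were lower. Alpha cell identity genes were lower in delta-like cells, with 6 of 11 (median -0.97), including the transcription factor gene Arx (13.8 and 1.89 CPM). After thinning, Gcg was found in 46.0% of WT and 26.4% of DB delta-like cells, against 35.1% and 34.7% of endothelial-like cells, so Gcg, Mafb and Arx can come from alpha cells or their transcripts mixed into the WT class and need not show a change in delta cells. NF-kB targets were higher in 12 of 13 cases (median 3.55), of which 7 of 13 reached 50% of their library level, while 14 of 21 interferon-stimulated genes were lower (median -0.74).

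PP-like cells, with 57 WT and 316 DB cells, had Ppy 1.55-fold and Pyy, the peptide YY gene, 1.80-fold higher in DB. Sst had 12606 UMIs in WT and 2276 in DB, and 21.1% of WT and 7.28% of DB cells drew more than 10% of their UMIs from insulin. The class therefore need not hold the same mix of cells in both libraries. The acute phase gene Fgb (17.7 and 234 CPM), Fgl2 (7.23-fold), Cxcl10 (12.2-fold), Irf1 (8.19-fold) and the NF-kB inhibitor genes Nfkbia (84.2 and 711 CPM) and Nfkbiz (9.49-fold) were higher. Lower genes were Lgals3, a galectin gene (21.4-fold), the filament gene Vim (16.8-fold), the glutathione transferase gene Gsta4 (14.8-fold), Ppp1r1a (10.2-fold) and Hspb1 (8.05-fold). NF-kB targets were higher in 10 of 12 cases (median 3.16), and 8 of 12 reached 50% of their library level.

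The fourth question was what differs in the duct, vessel and stromal cells of the islet preparation. Ductal-like cells (126 and 567 cells) had higher levels in DB of the neutrophil-attracting chemokine genes Cxcl5 (50.3-fold), Cxcl1 (54.4-fold) and Cxcl2 (67.1 and 2194 CPM). Of 18 NF-kB targets 15 were higher (median 1.64), and of 16 cell cycle genes 11 were higher (median 0.91), including Top2a, a topoisomerase gene (0.889 and 17.2 CPM), and the proliferation marker gene Mki67 (18.7-fold). Immunoglobulin genes were also higher, with 34 and 7987 UMIs of Igkc, 55.9-fold for Ighm and at least 41.5-fold for Jchain, which places B-lineage transcripts among these cells. The regenerating protein genes Reg2 (19.6-fold), Reg3b (6.23-fold) and Reg1 (4.37-fold) were lower, as were the kallikrein gene Klk1 (11.7-fold), the dynein light chain gene Dynll2 (2.95-fold) and Hspb1 (2.76-fold). Reg3b turned to a log2 ratio of 2.89 with every variable gene and 2.84 with separate clustering. Cells with over 10% insulin UMIs were 33.3% of WT and 10.8% of DB ductal-like cells.

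In endothelial-like cells (177 and 130 cells), Selp and Sele, which encode P-selectin and E-selectin, had 20.8 and 436 CPM and 4.90 and 83.9 CPM, and Vcam1, an adhesion molecule gene, 5.71 and 48.2 CPM. The mucosal addressin gene Madcam1 was 27.3-fold higher, with the stress gene Ankrd1 (30.1-fold), the granulocyte factor gene Csf3 (23.7-fold), the iron-binding lipocalin gene Lcn2 (56 and 593 UMIs) and Cxcl1 (21.7-fold). The vessel growth gene Apln was lower (69.4 and 8.31 CPM), and so were the collagen gene Col13a1 (6.51-fold), the channel subunit gene Kcne3 (84.9 and 12.5 CPM), the pentraxin gene Nptx1 (6.36-fold), Reg2 (23.7-fold) and Reg3b (19.4-fold). As a group, 24 endothelial genes split into 8 higher and 10 lower (median -0.41). NF-kB targets were higher in 12 of 15 cases (median 2.31), and 7 of 14 matrix genes were lower (median -0.72), such as Sparc, which encodes osteonectin (1976 and 737 CPM).

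Mesenchymal-like cells (226 and 197 cells) had nearly the whole list of interferon-stimulated genes lower in DB, 23 of 25, with a median of -1.67. The interferon-induced GTPase genes Iigp1 (124 and 10.1 CPM), Ifi47 (42.5 and 6.33 CPM) and Gbp7 (56.9 and 10.4 CPM) and the chemokine gene Cxcl9 (8.73-fold) were examples. Of 16 antigen presentation genes 14 were lower (median -1.31), including the class I gene H2-D1 (2062 and 523 CPM). The class joins cluster 14 (125 WT and 166 DB cells) and cluster 17 (101 and 31 cells), so these values also hold a difference in cell mix. Without cluster 17 the interferon median was -0.92 (13 of 21 lower) and the antigen presentation median -0.29 (2 of 10 lower), Iigp1 was 4.65-fold lower and Top2a 85.7-fold higher. Fibrosis and matrix genes were higher in 19 of 32 cases (median 0.77), including Timp1, a protease inhibitor gene (326 and 2448 CPM), the contractile gene Tagln (7.45-fold), the collagen gene Col1a1 (83.5 and 472 CPM) and Postn, the periostin gene. That median turned to -0.10 at the lower Leiden resolution and -0.12 with every variable gene, where the cell counts go with cluster 12 joining the class. Cell cycle genes were higher in 13 of 19 cases (median 0.72), with Top2a 21.2-fold and the histone gene Hist1h1b 22.9-fold higher, and Ankrd1 was 11.8-fold higher. The lymphocyte chemokine genes Cxcl13 (156 and 6.33 CPM) and Ccl5 (6.71-fold) and the guanine deaminase gene Gda (5.63-fold) were lower, although Ccl5 came to a log2 ratio of 0.05 with every variable gene. Transcripts of other cells were present too, with the leukocyte gene Cd52 (28.5-fold), the epithelial gene Wfdc18 (at least 68.7-fold) and the immunoglobulin gene Ighg3 (at least 224-fold) higher and Jchain (816 and 27 UMIs) and Ighm (13.3-fold) lower.

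The fifth question was how the immune cells of the islets differ. Macrophage-like cells (308 and 147 cells) had higher inflammatory genes in DB. Of 25 lipid-associated and inflammatory macrophage genes 18 were higher and 0 lower (median 1.26), including Spp1 (115 and 4800 CPM), Tnf (93.8 and 1621 CPM) and the cytokine genes Il1b (240 and 3296 CPM) and Ccl4 (309 and 3337 CPM). NF-kB targets were higher in 18 of 22 cases (median 1.85), such as Lcn2 (5.34 and 535 CPM). Of 23 immediate early and dissociation response genes 13 were higher (median 1.10), such as Egr1 (82.4 and 633 CPM). Of 14 glycolysis genes 7 were higher (median 0.62), with the hexokinase gene Hk2 3.56-fold and the lactate dehydrogenase gene Ldha 2.26-fold higher. Resident macrophage genes were level (median 0.07). The class II gene H2-Aa was 2.19-fold lower. Neutrophil and precursor genes were found in DB cells of this class with 0 UMIs in WT, namely S100a9 (9657 UMIs, at least 6849-fold), Camp (at least 1251-fold), Ngp (at least 1031-fold), Wfdc21 (at least 204-fold) and Mpo (at least 142-fold), so part of the class in DB resembles granulocytes. The higher inflammatory, NF-kB, immediate early and glycolysis genes of the class can reflect that mix of cells. They need not show a change in macrophages. The bridging protein gene Mfge8 was 155-fold higher. Immunoglobulin genes Jchain (482 and 1 UMIs, 40.5-fold to 8966-fold), Igkc (49.2-fold) and Ighm (24.5-fold) were lower, with Pkdcc (13.9-fold), Plcxd2 (12.9-fold) and Ccnf (10.0-fold). The direction of Jchain and Igkc turned in 2 and 4 settings.

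Across classes, NF-kB targets had a median at least 1.5-fold higher in 8 of 10 classes (1.14 log2 in B-like cells, which turned to -2.01 with free RNA subtracted, 0.50 in mesenchymal-like cells, or 1.71 without cluster 17, and -0.10 in T or NK-like cells), while interferon-stimulated and antigen presentation genes differed in direction from class to class.

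**Figure D3:**
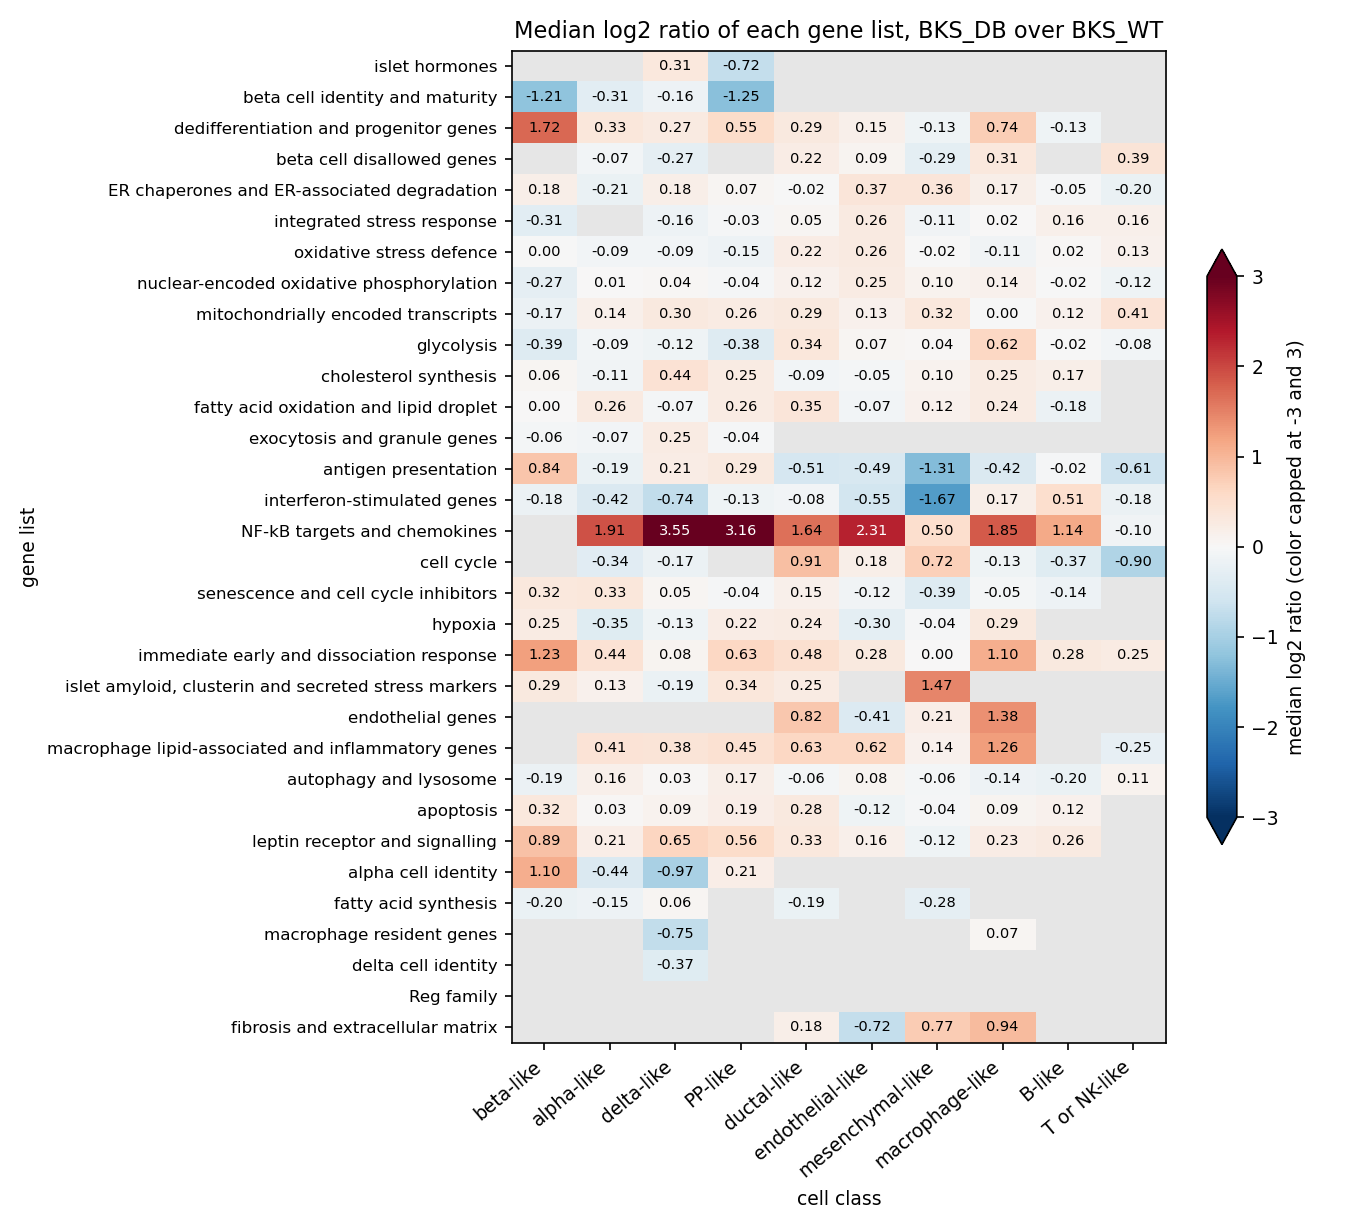
Median log2 ratio (DB over WT) of each gene list in each class. Grey cells had fewer than 5 measured members, or no more than 50% of their members reached 50% of the whole-library level.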

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

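The gene lists behind the first 4 values were chosen beforehand, and the pairs of classes, and mesenchymal-like cells without cluster 17, were compared after the results were seen. None of these differences between classes was tested, since each genotype has 1 library.

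Antigen presentation genes stood out because they went opposite ways in different cell types of the same 2 libraries. Their median log2 ratio was 0.84 in beta-like and -0.61 in T or NK-like cells, a difference of 1.45, and -1.31 in mesenchymal-like cells, a difference of 2.15. The mesenchymal median was -0.29 without cluster 17, which held more WT than DB cells, so part of that gap goes with the mix of cells and the 10 members measured there. The class I gene H2-Q6 shows it, with 0.870 and 5.23 CPM in beta-like cells but 3.79-fold lower in DB mesenchymal-like cells. In T or NK-like cells the invariant chain gene Cd74 was 2.78-fold lower, but so were the cytotoxic genes Gzma (336 and 3 UMIs) and Nkg7 (377 and 32.9 CPM), the adaptor gene Tyrobp (10.3-fold) and the transcription factor gene Irf8 (8.07-fold), while Il17a was higher (0 and 86 UMIs), so the T or NK values can reflect another mix of cells in the class.

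Cell cycle genes also went opposite ways. Their median was 0.91 in ductal-like and -0.90 in T or NK-like cells, a difference of 1.81, and 0.72 in mesenchymal-like cells, a difference of 1.62 from T or NK-like cells. Top2a was 21.2-fold higher in DB mesenchymal-like cells and 2.72-fold lower in DB T or NK-like cells. The same limit on the mix of T or NK-like cells holds here, and the ductal-like class gained B-lineage transcripts in DB (34 and 7987 UMIs of Igkc), so these gaps are not shown to arise within 1 kind of cell.

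The remaining values come from clusters outside every named class of the main setting, singled out because DB exceeded WT there. By its cell counts, cluster 12 fell in the mesenchymal-like class at the lower Leiden resolution. Cluster 12 held 4.69% of DB cells and 0.324% of WT cells, and its leading genes included the protease inhibitor gene Slpi, the crystallin gene Cryab, the prostaglandin synthase genes Ptgs2 and Ptgis, the activin subunit gene Inhba and the chemokine gene Cxcl2. Cluster 16 held 2.83% of DB cells and 0 WT cells, with an exact upper limit of 0.0543%, and it was led by the trypsinogen genes Prss1, Prss3 and Try5 while its median cell drew 43.1% of UMIs from insulin. Reads of trypsinogen genes can be shared among paralogs. These differences between the libraries were not tested either.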

How the results depend on the processing

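Chosen after the data were seen were leaving out mixed insulin cells, leaving out the beta cluster led by Nos2 or the smaller mesenchymal cluster, subtracting free RNA by the hormone estimate, members of at least 10 CPM, and endocrine classes by leading hormone. No paired analysis was possible because each genotype has 1 library and no result comes from a test. Unless a reason is given, the cause of a change was not tested. A value counted as the same inside the interval of the main value, and otherwise as moved. It counted as reversed when it crossed no difference from a main value whose interval excluded no difference. For lists and genes that main value also had to be at least 1.5-fold. Crossings from other main values count as the same or moved.

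Of shares of kept cells (DB over WT) in 10 classes, 49 of 79 values from other settings stayed the same, 25 moved and 5 reversed. Of endocrine shares 15 of 31 stayed, 15 moved and 1 reversed. By direction alone, 10 of the 79 and 9 of the 31 lay on the other side of equal from the main value. Without a cell filter the ratios were 2.21 for B, 1.29 for T or NK, 0.833 for alpha (PP included), 1.17 for beta, 1.01 for delta, 6.76 for ductal, 0.961 for endothelial, 0.583 for macrophage and 1.24 for mesenchymal cells. The stricter filter gave 0.933 for B, 0.481 for T or NK and 1.01 for beta cells, and it removes small cells by construction, with a median of 4131 UMIs in WT and 2397 in DB B-like cells. With doublets kept the ratios were 1.64 for PP, 0.377 for alpha and 0.737 for delta cells. Clustering on every variable gene gave 8.91 for PP, 1.02 for beta, 0.623 for delta, 0.493 for endothelial and 2.05 for mesenchymal cells. Leiden resolution 0.5 gave 0.631 for alpha (PP included), 0.713 for delta and 2.04 for mesenchymal cells, and resolution 2 gave 0.669 for delta cells. Naming by leading hormone gave 0.398 for alpha cells. Separate clustering gave 0.815 for beta, 5.21 for ductal and 0.550 for mesenchymal cells, and 0.968 for beta among endocrine cells. Leaving out mixed insulin cells gave 0.745 for delta and 5.76 for ductal cells. At resolution 0.5 and without a filter PP-like cells merged with alpha-like cells, so the alpha values there count both and cannot be set beside the others, and separate clustering gave no value for alpha, delta or PP.

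For the 11 beta gene lists of most interest 189 of 198 medians were the same, 9 moved and 0 reversed. For the 12 others 211 of 216 were the same. By sign alone, 2 of the 198 and 24 of the 216 lay on the other side of 0. These counts cannot be ranked against those of shares. List intervals come from a bootstrap over members, and share intervals hold counting error only. Free RNA subtraction by the first estimate moved alpha identity to 4.89, chaperones to 0.29, oxidative phosphorylation to -0.32, glycolysis to -0.81 and interferon-stimulated genes to -0.96. It left 7 NF-kB members and 7 antigen presentation members higher. It also brought NF-kB targets to -2.01 in B and -0.63 in alpha cells. Its estimate came from acinar enzymes, 56.5% of the library level in DB. Plain CPM gave 0.38 for chaperones, -0.0747 for oxidative phosphorylation and -0.19 for glycolysis, by its shift of 0.20 of all genes. Without the cluster led by Nos2 the interferon median was -0.37. For antigen presentation 7 members were higher at 2-fold and 6 among members of at least 10 CPM, both narrower by construction. In mesenchymal cells the fibrosis median was -0.10 at resolution 0.5 and -0.12 with every variable gene, both with cell counts that go with cluster 12 joining the class. In other classes 3258 of 3572 list values were the same, 310 moved and 4 reversed. By sign alone, 358 of the 3572 lay on the other side of 0 from the main value.

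Without thinning the share ratios were 105 for Cck and 12.7 for Gast, against 541 and 34.5 with thinning, where the Cck ratio rests on 2 WT cells (135 to 2164). Of 2439 values for 153 named genes 1810 were the same, 617 moved and 12 reversed. By sign alone, 41 lay on the other side of 0, the 12 reversed among them. The reversed log2 ratios were Ins2 in delta cells (-0.0570 at resolution 2, -0.14 with every variable gene, -0.47 with free RNA subtracted), Reg3b in ductal cells (2.89 with every variable gene, 2.84 with separate clustering), Jchain in macrophages (0.11 with doublets kept, 0.16 without a filter), Igkc in macrophages (0.30 with doublets kept, 2.22 with separate clustering, 0.34 without a filter, 2.13 with the stricter filter) and Ccl5 in mesenchymal cells (0.0518 with every variable gene). Depth limits T or NK cells most, with 1745 genes measured against 13074 in beta cells.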

Other observations

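B-like cells, summed as a class, differed in antibody heavy and light chain genes. The class joins cluster 5 (342 WT and 631 DB cells) and cluster 19 (43 and 47 cells). Cells carrying these transcripts were not counted, so a few cells may hold most of them. In DB the IgG genes Ighg1 (0 and 1949 UMIs, at least 635-fold), Ighg2c (3 and 624 UMIs, 69.2-fold to 988-fold) and Ighg3 (62.2 and 935 CPM) were higher, while the IgA gene Igha (1064 and 9 UMIs), the IgG gene Ighg2b (11.6-fold) and the light chain gene Iglc3 (5.36-fold) were higher in WT. Counts of similar immunoglobulin genes can be exchanged among paralogs. Of 23 interferon-stimulated genes 9 were higher and 0 lower in DB (median 0.51), such as Ifit2 (46.9 and 99.9 CPM) and Irf1 (56.3 and 117 CPM), and the interferon-induced membrane protein genes Ifitm1 and Ifitm2 were 56.2-fold and 5.33-fold higher. The chemokine gene Ccl4 was 23.8-fold higher. Of 22 cell cycle genes 10 were lower (median -0.37), and Scand1 (3.58-fold), Ndfip1 (2.94-fold) and Imp3 (2.90-fold) were lower too.

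In T or NK-like cells the interleukin genes Il17a (0 and 86 UMIs, at least 45.3-fold) and Il22 (208 and 1460 CPM) were higher in DB, as was the neuropeptide gene Calca (4.17-fold), with AA467197 (55.6 and 200 CPM) and Ldlrad4 (41.7 and 148 CPM). Lower genes were the granzyme gene Gzma (336 and 3 UMIs), the cytotoxic granule gene Nkg7 (377 and 32.9 CPM) and the adaptor gene Tyrobp (10.3-fold), together with the growth factor gene Areg (368 and 35.7 CPM), the transcription factor gene Irf8 (8.07-fold) and Hist1h1b (10.1-fold). The trypsinogen gene Prss3 (1 and 74 UMIs) can be free acinar RNA, which was not tested. Acinar enzymes stood at 18.1% of their whole-library level in WT and 56.5% in DB T or NK-like cells. In beta-like cells, 7 of 17 apoptosis genes were higher (median 0.32), including the caspase gene Casp3 (5.85 and 12.4 CPM), and 5 of 15 senescence genes (median 0.32), including the decoy receptor gene Tnfrsf11b (1.84 and 31.8 CPM).

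The tests below on scaling, dilution, free RNA in cluster 7, doublets, NF-kB targets over all classes and free Ppy were chosen only after the results were seen, and those without the cluster led by Nos2 and by leading hormone were chosen after the data were seen but before their own values.

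Identity genes were lower in DB beta-like cells (median -1.21). Scaling by a few abundant genes does not account for it, since the other scalings left the median at -1.01 or further from 0. Dilution by RNA of other cells was expected to lower Ins1, Ins2 and Iapp by about as much as the list. Ins1 was 2.06-fold lower, Ins2 1.17-fold lower and Iapp 1.12-fold higher (median -0.23). These values cannot decide on dilution by free RNA, because that RNA would carry the same transcripts. Islet hormones made up 50.3% of the WT and 46.2% of the DB UMIs of kept cells. The cluster led by Nos2 does not account for the lower identity genes, since the list median without it was -1.07. Preparation or culture of a library cannot be told apart from genotype with 1 library per genotype, and an effect of the genotype itself may hold but was not tested.

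NF-kB targets were higher in DB beta-like cells. Free RNA does not explain cluster 7, where the list stood 1.72 above the other beta clusters of the same library, but for those clusters it cannot be told apart, because their median lay 0.46 (bootstrap -0.16 to 0.70) above the class where each gene is lowest. Doublets with macrophage, mesenchymal or endothelial cells would bring the markers of those cells, whose largest median level was 0.0654% of the class level in cluster 7. In clusters 2 and 4 the median list gene stood at least 32.2 times as high as the median marker. The highest macrophage and mesenchymal markers there (3.95% and 3.98%) exceeded the median list genes (1.45% and 2.02%), so by that measure these doublets are not excluded. The highest endothelial marker (0.596%) stayed below the median list gene (10.3%). In cluster 7 list genes reached 58.7% of the ductal level while the highest ductal marker reached 29.5%, which argues against ductal doublets there, but in clusters 2 and 4 list genes (5.68%) and ductal markers (median 4.83%) stood alike, so the values that ductal doublets would need are present. The list was at least 1.5-fold higher in 8 of 10 classes, so a response of the DB library to preparation or culture stays open beside genotype, which was not tested. With free RNA subtracted the median turned to -2.01 in B-like and -0.63 in alpha-like cells. Free RNA is therefore not excluded as part of that spread over classes.

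PP-like cells were a larger and alpha-like cells a smaller share in DB. Free Ppy RNA does not explain it, since Ppy in DB B-like cells was 0.262% of its level in PP-like cells. Misnaming by the clustering is argued against by the leading hormone, which gave a PP ratio of 4.46. Over every barcode the alpha ratio by leading hormone was 0.518, but this cannot exclude loss of alpha cells in the filter. Insulin made up 11.7% of UMIs in failing WT and 8.14% in failing DB barcodes, so the 5% rule can name such barcodes beta-like. From kept cells to every barcode, WT beta-like counts rose from 4155 to 8491 and WT alpha-like counts from 869 to 929. The part of the pancreas sampled and survival in culture cannot be told apart from genotype with 1 library per genotype, and genotype was not tested.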
